A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

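Per the labels, yeast was grown in YPD, a rich glucose medium, at 25 C to an optical density of 0.8, harvested at room temperature and frozen. Total RNA was extracted with hot phenol and poly(A) RNA was purified on oligo-dT cellulose. Polyadenylated Bacillus subtilis transcripts were added in proportion to culture density as spike-in controls. Reverse transcription with aminoallyl-dUTP was followed by coupling to Cy3 and Cy5. Per the labels, each of the 4 samples had 2 channels and named 2 scans of opposite dye orientation, and the deposited values hold 1 value per probe. How the authors combined the scans, and whether both held the same RNA or RNA of separate cultures, is not given in the sources used here. Each sample was therefore treated as 1 measurement. Channel 1 held the named strain and channel 2 its wild type, so a positive value is higher in the named strain.

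The deposited values lie around 0 with both signs and were read as log2 ratios. Base 2 is an assumption, since the sources used here do not state the base, the centring, the background correction or the filters, nor whether the spike-ins set the scale. The scanner software is not given in the sources used here either. The direction follows the channel labels and was checked on SNF2 in the null. The medians of the deposited values were -0.12 for BY4741, 0.10 for Snf2-2FLAG, -0.39 for the SnAC deletion and 0.003 for the null. The number of arrays, 1 per group, limits the precision. Probes without a value numbered 396, 531, 307 and 165 in the same order, and only 33 probes had none on any array.

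Gene names came from the platform annotation: 5578 of 6226 probes had 1 gene name, 648 had none and 0 had several. Of the named probes, 5573 matched the R64 gene table of the yeast reference, which served for current symbols and gene neighbours only, and 5 kept the name of the annotation. No coordinates are given because the values name no genome build. Probes of the same gene were averaged, which concerned 30 genes and 61 probes, and unnamed probes were kept singly, giving 6195 features with 5547 named genes. Probes of the same gene differed by a median of 0.107 log2 in BY4741, 0.126 in Snf2-2FLAG, 0.135 in the SnAC deletion and 0.085 in the null.

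With 1 sample per group no statistical test was possible. A feature passed the size rule if its ratio was at least 2-fold from 1 and lay outside the central 99% of the wild-type array of its own background. The bound from the wild-type arrays never exceeded 2-fold, so it removed no feature. Genes named in the text are, for each mutant, the 10 highest and 10 lowest named genes past the rule, up to 4 members of each list with the largest size, the SWI/SNF subunits, and the 5 largest differences between the mutants in each direction among those past the rule in at least 1. Genes outside this choice are identified as such where they appear, except that SUC2, INO1 and HO, members of a preset list, and gene neighbours of SNF2 were added for context. For 38 lists of genes fixed before the data were examined, the median relative to the array median was ranked among 10000 random lists of the same size. No signal level is given, so the lists were not matched on expression. The result of 1 of the 38 lists is not reported here, though the list is included in the counts of lists. A further 7 lists were drawn up after the data were seen. The percentiles describe these arrays and are not p-values.

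The mutants were compared by Pearson and Spearman correlation across features and by the overlap of features past the rule, set beside the overlap of independent lists. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with matplotlib 3.10.9 for the plots. The procedure was tested on simulated data built from the wild-type arrays, whose spread covers technical noise only if both channels held the same RNA. For the null, it recovered 98.0% of features changed 3-fold in either direction and called 4 of 5831 unchanged ones. The BY4741 array behind this simulation was narrower than the null array. Their SDs, estimated from the median absolute deviation, were 0.14 and 0.255, so more unchanged features may be called on the null array. For the SnAC deletion as deposited, with its displaced median, the procedure recovered 72.0% of features 3-fold higher and 100% of those 3-fold lower. It called 49 of 5690 unchanged ones. After centring it recovered 98.0% and 100% and called 20 of 5690. Alternatives tried were folds of 1.5 and 3, median centring, subtraction of the wild-type array, removal of features variable in wild type, features measured on all 4 arrays, no bound from the wild-type arrays, other random lists, and Spearman correlation. Removal of Ty reading frames, of unnamed probes and of features past the rule were added after the data were seen.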

Results

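Messenger RNA from 4 budding yeast samples was compared on spotted DNA microarrays with 2 colours. Snf2 is the ATPase that drives SWI/SNF, a complex that moves and evicts nucleosomes, and SnAC is a conserved domain of Snf2. The design asked how deleting parts of Snf2 alters expression. It held 1 sample in each of 4 groups: a strain without SNF2 hybridised against wild-type BY4741, a strain lacking only the SnAC domain hybridised against its wild type Snf2-2FLAG, and each of these 2 wild types hybridised against itself. BY4741 is a standard laboratory strain of mating type a, and Snf2-2FLAG carries an epitope tag on Snf2. There was 1 value per probe and group and no replicates, so no value below has a replicate error and none was tested. The 2 wild-type hybridisations give the spread of ratios without a genotype difference. Whether their 2 channels held RNA of separate cultures is not given in the sources used here, and if they did not, this spread covers technical noise only. Values are deposited log ratios, read as log2, and folds hold only if that base is right. Of 6226 probes, 5830 had a value on the BY4741 array, 5695 on the Snf2-2FLAG array, 5919 on the SnAC deletion array and 6061 on the null array.

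On the wild-type arrays, genes of protein folding and stress lay at the low end and genes for making ribosomes at the high end, although both channels held the same strain. The small heat shock protein HSP42 read -1.30 in BY4741 and -1.31 in Snf2-2FLAG, and the disaggregase HSP104 read -1.12 and -1.23. GLK1, a glucokinase, read -1.001 and -1.217, and TSL1, a subunit of trehalose synthase, read -1.19 and -1.13. HSP42 and HSP104 were picked after their values were seen. Relative to the median of the array, the general stress genes under Msn2 and Msn4 had a median of -0.33 in BY4741 and -0.39 in Snf2-2FLAG. Heat shock proteins under Hsf1 had medians of -0.40 and -0.51. Ribosome biogenesis genes had medians of 0.26 and 0.48, and subunits of RNA polymerase I and III had medians of 0.21 and 0.27. Each of these 8 medians lay outside the central 95% of 10000 random lists of the same size. Ribosomal protein genes did not share this pattern on both arrays. Their median was 0.12 in BY4741, above random lists, and -0.09 in Snf2-2FLAG, below them.

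Over all features of the wild-type arrays, the log2 ratio had an SD across features of 0.16 in BY4741 and 0.25 in Snf2-2FLAG, and its central 99% ran from -0.62 to 0.31 and from -0.63 to 0.85. In BY4741, 2 features were at least 2-fold higher and 5 at least 2-fold lower, out of 5808. In Snf2-2FLAG, 9 were higher and 9 lower, out of 5669. The adjacent genes BSC1, YDL038C and PRM7 had the highest values on the Snf2-2FLAG array, at 1.89, 1.89 and 1.99. The latter 2 were named after their values were seen. The medians of all features were -0.12 and 0.10, and the 2 arrays correlated across genes with a Pearson r of 0.45 and a Spearman rho of 0.34. Genes are not independent replicates, so these coefficients only describe the arrays.

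**Figure D1:**
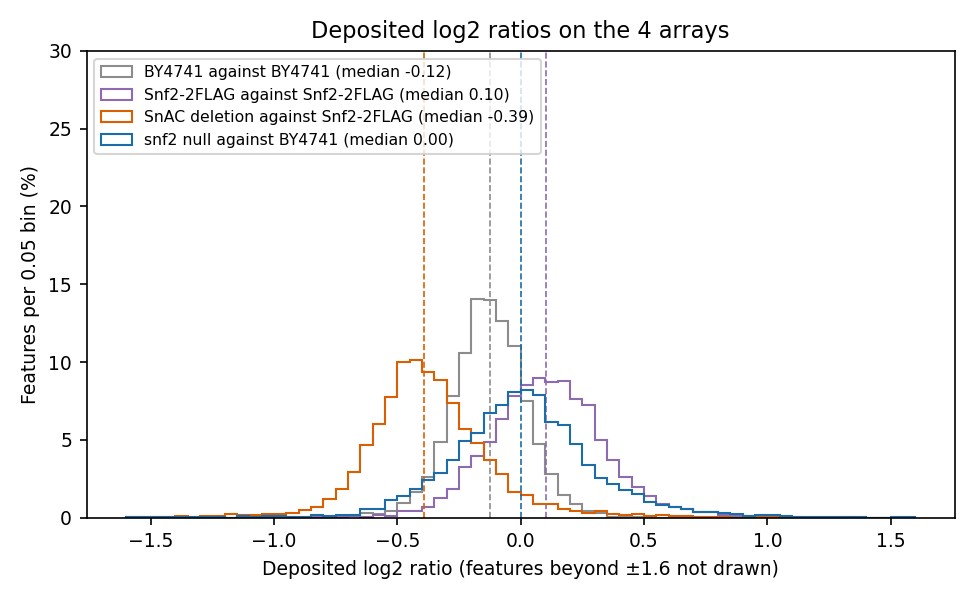
Histograms of the deposited log2 ratio of each of the 4 arrays, as the percentage of features in each bin, with a dashed line at each median. The SnAC deletion array lies to the left, with a median of -0.39, while the null array is centred near 0 and the wild-type arrays have medians of -0.12 and 0.10.

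In the null, SNF2 itself (YOR290C) read -2.14, against -0.32 on the BY4741 array. With the gene deleted, its probe can read only background or cross-hybridisation, so this value gives the direction and no exact fold. It had no value on the SnAC deletion or Snf2-2FLAG arrays, so the domain deletion could not be checked in this way. Transcripts of the other SWI/SNF subunits stayed inside the size rule in both mutants. In the null they ran from -0.24 for RTT102 to 0.38 for SNF6, and the core subunits SWI1, SWI3 and SNF5 read 0.19, 0.09 and 0.25. The genes beside SNF2 read 0.29 for YOR289W and 0.49 for YPK9 in the null. Subunits of the related remodeler RSC had a median of -0.02 in the null and -0.01 in the SnAC deletion, each relative to its array.

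The comparison of the null with BY4741 asked which transcripts depend on Snf2. Genes for taking up and storing phosphate were far lower in the null, and genes for taking up and reducing sulphate were far higher. The acid phosphatases PHO11 (YAR071W) and PHO12 (YHR215W) were 34.4-fold and 29.1-fold lower, and the phosphate transporter PHO84 (YML123C) was 26.7-fold lower. SER3 (YER081W), an enzyme of serine synthesis, was 29.7-fold higher, above the ATP sulphurylase MET3 (YJR010W) at 15.4-fold and the membrane-active stress protein HSP12 (YFL014W) at 11.7-fold. YHB1 (YGR234W), which detoxifies nitric oxide, was 24.3-fold lower. By the size rule, which needs a ratio of at least 2-fold outside the central 99% of the BY4741 array, 76 of 6031 features were higher and 95 were lower, 2.84% of those measured. Named genes made up 69 of the higher and 86 of the lower features. Subtracting the BY4741 array turned the balance, to 155 higher and 78 lower. The median of that array was -0.12, so subtraction without centring moves most values up.

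Of 18 measured genes of the phosphate regulon, 13 passed the size rule in the null, all lower. The list had a median of -1.94 relative to the array, below all random lists of its size, against 0.07 on the BY4741 array. PHO5, the main repressible acid phosphatase, read -2.85, and VTC3, a subunit of the polyphosphate polymerase, read -3.03. The vacuolar phosphatase PHO8 read -1.36, and PHO3, an acid phosphatase placed on this list and on that for thiamine, read -2.002. PHO11 and PHO12 are near-identical in sequence, so their probes may report on both and the 2 values are not separate evidence.

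Of 23 measured genes of methionine synthesis and sulphur assimilation, 14 passed the rule in the null, all higher, and the median was 1.21 against -0.02 on the BY4741 array. SUL2, a sulphate permease, read 3.15. MET6, the methionine synthase, read 2.58, and MET2, the homoserine acetyltransferase, read 2.09. Among 7 genes of serine synthesis and breakdown, the isoenzyme pair SER3 and SER33 were higher at 4.89 and 1.40, and their sequences are similar enough that cross-hybridisation is possible. The 3 genes that encode only the glycine cleavage complex were lower, with GCV1 at -1.75, GCV2 at -1.11 and GCV3 at -1.01, while their shared subunit LPD1 read 0.23. That list was drawn up after the data were seen.

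General stress genes under Msn2 and Msn4 had a median of 0.53 in the null, with 6 of 29 measured members higher and 0 lower. HSP12 read 3.54, TSL1 2.12, GLK1 1.83 and YGP1, a secreted glycoprotein of starved cells, 1.32. The same list had a median of -0.33 on the BY4741 array, where TSL1 read -1.19 and GLK1 -1.001. Heat shock proteins under Hsf1 had a median of -0.07 and 0 of 20 members past the rule. Genes of respiration were moderately higher as groups. The TCA cycle list had a median of 0.49, with IDH1, a subunit of isocitrate dehydrogenase, past the rule at 1.17. Oxidative phosphorylation had a median of 0.50 with 0 of 30 genes past the rule. ALD4, the mitochondrial aldehyde dehydrogenase, read 1.81, and AAC1, an ADP/ATP carrier of the mitochondrial membrane, read 2.35.

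Genes of translation were lower in the null by small amounts. Of 131 measured ribosomal protein genes none passed the size rule, yet their median of -0.45 lay below that of all random lists, against 0.12 on the BY4741 array. RPS22A read -0.75 and RPS28B -0.62. Ribosome biogenesis genes had a median of -0.33, with BRX1 at -0.52 and NHP2 at -0.53, and RNA polymerase I and III subunits had a median of -0.28. Both lists lay on the high side of the BY4741 array, at 0.26 and 0.21. Histone genes were higher, with a median of 0.31 and HHT2 at 0.69, and 0 of 10 passed the rule.

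Some mating and metal uptake genes were lower in the null. Of 17 a-specific and pheromone response genes, 4 were lower past the rule, and the median was -0.46. These were the a-factor genes MFA1 at -1.66 and MFA2 at -1.43, the protease gene BAR1 at -1.38, and SST2, which damps pheromone signalling, at -1.03. The genes specific to alpha cells had a median of 0.05. Of 24 genes of the iron regulon, 5 were lower and the median was -0.24. They included the siderophore transporters SIT1 at -2.81, ENB1 at -1.53, ARN1 at -1.53 and ARN2 at -1.44. Copper genes had a median of -0.61 with none of 9 past the rule, against 0.02 on the BY4741 array. The zinc regulon had a median of 0.004, and the zinc transporter gene ZRT1 was its only member past the rule, at -1.38.

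Retrotransposon reading frames were also low in the null. The Ty1 and Ty2 open reading frames, a list drawn up after the data were seen, had 9 of 23 members measured. All 9 were lower, with a median of -3.09. On the BY4741 array 19 members had a value, so the null values cover only part of the list. YJR026W read -4.04 and YBL005W-A -3.59. Ty copies are nearly identical, so these probes count as a single family signal. CAR2, which breaks down ornithine, read -3.12. The anaerobic cell wall gene TIR1 read -2.95, although its list of seripauperin and anaerobic cell wall genes had a median of 0.13. In the opposite direction ARG1 and ARG4, the last enzymes of arginine synthesis, read 2.08 and 1.34, although the whole list of amino acid genes under Gcn4 had a median of 0.04. The subtelomeric COS and Y prime helicase families had a median of 0.47 and COS8 read 0.80, with none past the rule.

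Several genes often studied with SWI/SNF were within the rule in the null. The cells grew in a rich glucose medium, and no signal level shows whether these genes were expressed in the wild type. A ratio near 0 therefore does not show that a gene is independent of Snf2. SUC2, the invertase, read 0.31 and INO1, for inositol synthesis, read -0.15, while HO had no value in either mutant. SUC2 and INO1 were on a list of 13 measured classic SWI/SNF-dependent genes, of which only PHO84, PHO5 and PHO8 passed, and its median was -0.02. Galactose genes had a median of 0.08 and G2/M genes of -0.04. Hexose transporters had a median of 0.18, which turned to -0.061 when the BY4741 array was subtracted. Thiamine synthesis genes had a median of 0.44 and glycolysis genes 0.15, with THI5 at 0.85. Across the 38 lists drawn up beforehand, 11 lay above and 8 below the central 95% of random lists in the null, where chance would give 1.9 in all. On the BY4741 array 15 lists lay outside, so a list outside random lists is not by itself a mark of genotype.

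The comparison of the SnAC deletion with Snf2-2FLAG asked the same of the domain. Phosphate and sulphur genes again stood at the ends of the array: PHO84 was 39.5-fold lower as deposited, PHO11 29.1-fold and YHB1 18.5-fold lower, while SER3 was 17.6-fold and MET3 9.86-fold higher. The whole array was displaced, however, with 93.2% of features below 0 and a median of -0.39, a factor of 1.31. Relative to that median, PHO84 was 30.1-fold lower, SER3 23.1-fold higher and MET3 13.0-fold higher. As deposited, 20 of 5890 features were higher and 145 lower, so 12.1% of those past the rule were higher. With the array centred on its median, 51 were higher and 70 lower, or 42.1% higher. Subtracting the Snf2-2FLAG array gave 33 higher and 489 lower. The median of that array was 0.10, so subtraction without centring moves most features of the SnAC deletion array further down. How many of the 489 reflect that displacement was not tested. The values of the SnAC deletion that follow are relative to the array median, and the counts are for the centred array unless said to be as deposited.

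Of 17 measured phosphate genes, 11 were lower in the SnAC deletion, or 13 as deposited, and the median was -1.35 against 0.12 on the Snf2-2FLAG array. PHO12 read -4.16, VTC3 -2.73, PHO5 -2.21 and PHO8 -1.30. Of 23 sulphur and methionine genes, 12 were higher, or 8 as deposited, and the median was 1.19 against -0.05. SUL2 read 2.84, MET6 1.89, MET2 1.72 and MET10, a subunit of sulphite reductase, 1.49. SER33 read 1.03 beside SER3 at 4.53. The glycine cleavage genes GCV1, GCV2 and GCV3 read -2.55, -1.43 and -1.05, all past the rule.

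General stress genes had a median of 0.70 in the SnAC deletion, with 7 of 30 members higher and 4 as deposited, against -0.39 on the Snf2-2FLAG array. HSP12 read 2.86, and on the Snf2-2FLAG array it read 0.78 relative to the median of that array. TSL1 read 2.16, YGP1 1.499 and GLK1 1.46. Histone genes had a median of 0.59, with HHF1 at 0.85, and oxidative phosphorylation genes had a median of 0.43. Both medians stayed above 0 as deposited, at 0.19 and 0.04. The TCA cycle median was 0.22 and turned to -0.17 as deposited. On the Snf2-2FLAG array the medians of these 3 lists were -0.28, -0.31 and -0.43. Heat shock proteins under Hsf1 had a median of -0.11, which turned to 0.38 when the Snf2-2FLAG array was subtracted.

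Ribosomal protein genes had a median of -0.20 and ribosome biogenesis genes one of -0.22 in the SnAC deletion, with none of 131 and none of 45 past the rule. These lists had medians of -0.09 and 0.48 on the Snf2-2FLAG array. Of 18 a-specific and pheromone genes, 3 were lower, or 7 as deposited, with BAR1 at -1.20, MFA1 at -1.11 and FAR1, an inhibitor of the cyclin-dependent kinase, at -1.05. Amino acid genes under Gcn4 had a median of -0.19, and 2 of 39 were lower, HIS4 at -1.54 and ASN1 at -1.26. As deposited, 5 were lower. Copper genes had a median of -0.55, against -0.22 on the Snf2-2FLAG array, and iron genes one of 0.01.

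Within the iron regulon the members of the SnAC deletion went both ways after centring, with 1 of 23 higher and 3 lower past the rule. As deposited, 0 were higher and 6 lower. The siderophore transporters SIT1, ARN2 and ENB1 were lower at -1.98, -1.53 and -1.09, while FIT3, a cell wall protein that retains iron, was higher at 1.18. FIT3 read 0.79 as deposited, which is within the rule. Of 23 Ty open reading frames, 10 had a value, against 16 on the Snf2-2FLAG array. All 10 were lower, with a median of -2.21 against 0.54 on the Snf2-2FLAG array. BSC1 read -2.66, and it is also among the highest genes of the Snf2-2FLAG array. SUC2 read 0.16 and INO1 read 0.03. Hexose transporters, thiamine synthesis genes and cell wall mannoproteins had medians of 0.21, 0.25 and 0.19, which turned to -0.18, -0.14 and -0.20 as deposited. Of the 38 lists, 11 lay above and 8 below the central 95% of random lists, and 13 lay outside on the Snf2-2FLAG array.

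Set against each other, the mutants showed largely parallel profiles. SER3, MET3, SUL2, HSP12, RTS3, MET6, TSL1 and AAC1 were among the 10 highest named genes of both, and PHO84, PHO11, PHO12, YHB1, YJR026W and YBL005W-A were among the 10 lowest of both. Across 5790 features Pearson's r was 0.88, with 0.864 to 0.899 as the central 95% of resampled features, and Spearman's rho was 0.77. The range describes the spread across features, which are not independent, on 1 array per mutant. It does not describe the spread between cultures. Each mutant correlated with each wild-type array below 0, from r of -0.17 to -0.26. As deposited, 19 features were higher in both and 84 lower in both, where independent lists of those lengths would share 0.243 and 2.19. After centring, 42 were higher in both and 64 lower in both, against 0.639 and 1.07, and on neither scale did a feature pass the rule in opposite directions. The mutants were grown and hybridised against different wild types, so genotype and strain background are not separated.

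**Figure D2:**
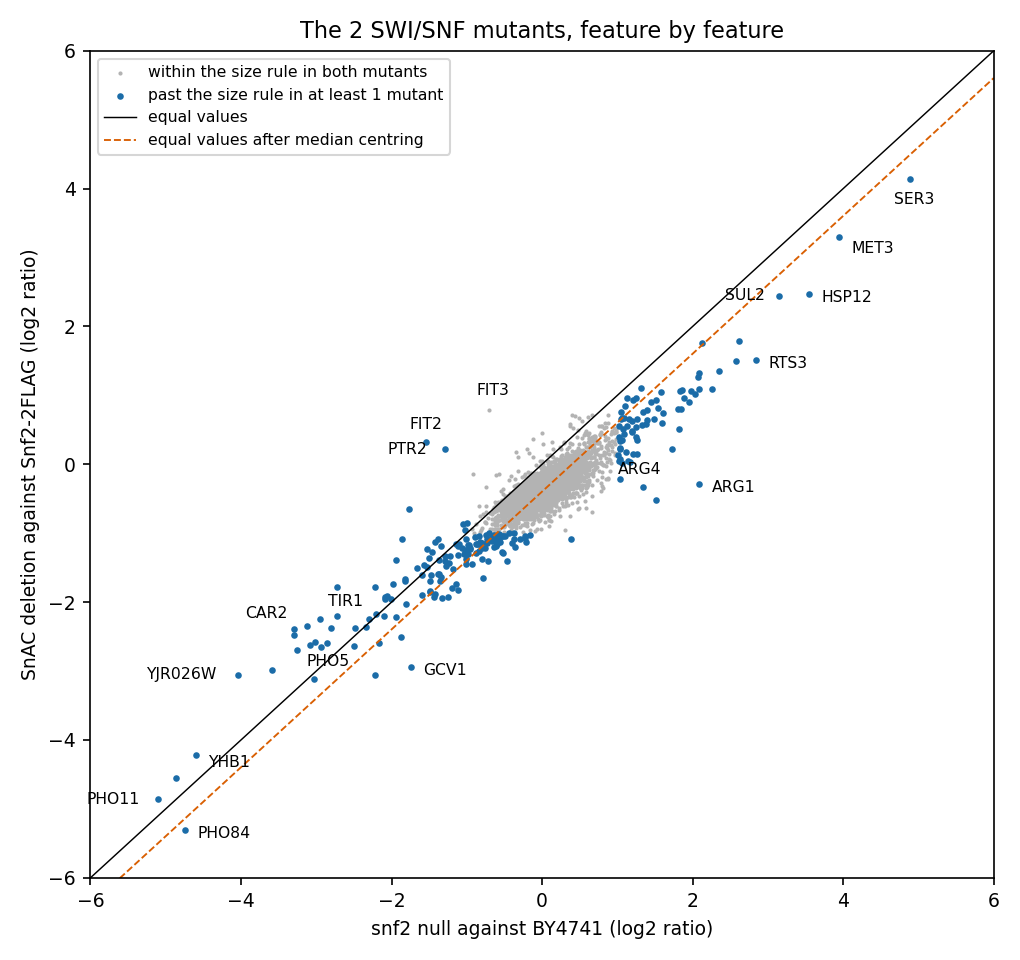
Each point is a feature measured in both mutants, with the deposited log2 ratio of the null on the horizontal axis and of the SnAC deletion on the vertical axis. Most points lie along the dashed line, which marks equal values after median centring, with r of 0.88, while FIT2, FIT3, PTR2, ARG1 and ARG4 lie away from it.

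After centring, features past the rule in both mutants mostly lay further from the median in the null. This set, chosen after the data were seen, does not select on either mutant alone. Of 42 features higher in both, 34 were further out in the null, 81.0%, with a median difference of 0.34. Of 64 lower in both, 51 were further out in the null, 79.7%, with a median difference of -0.37. As deposited, where the median of -0.39 moves all SnAC values down, 19 of 19 features higher in both and 39 of 84 lower in both, 46.4%, were further from 0 in the null. The null array was also wider over all features, with an SD of 0.44 against 0.36 on the SnAC deletion array. Estimated from the median absolute deviation, the SD was 0.255 against 0.205. A wider scale of the whole null array and larger changes in the null cannot be told apart here. The differences that follow are after centring. RTS3 was higher by 0.94 in the null than in the SnAC deletion, and the transcription factor gene ADR1 by 0.91. The Ty reading frame YJR026W differed by -1.37, and ZEO1 by -1.33. PHO84 and GCV1 were among the exceptions after centring, with -4.91 and -2.55 in the SnAC deletion against -4.74 and -1.75 in the null. These differences rest on a single array each and were not tested.

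FIT2, a cell wall protein that retains iron, read -1.55 in the null and 0.72 in the SnAC deletion relative to the array medians, and the peptide transporter PTR2 read -1.29 and 0.61. INA1 read -1.77 and -0.26. ARG1 was higher by 1.97 in the null, at 2.08 against 0.11, and ARG4 by 1.27. YOR338W read 0.38 in the null and -0.70 in the SnAC deletion. Of the 38 lists, 15 held no gene past the rule in either mutant on either scale. Of these, 8 also had medians inside random lists in both mutants, among them the RSC subunits, other remodelers, the galactose genes, flocculins, the proteasome and meiosis genes. The others, such as ribosomal proteins, ribosome biogenesis, histones and oxidative phosphorylation, had medians outside random lists in at least 1 mutant.

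**Figure D3:**
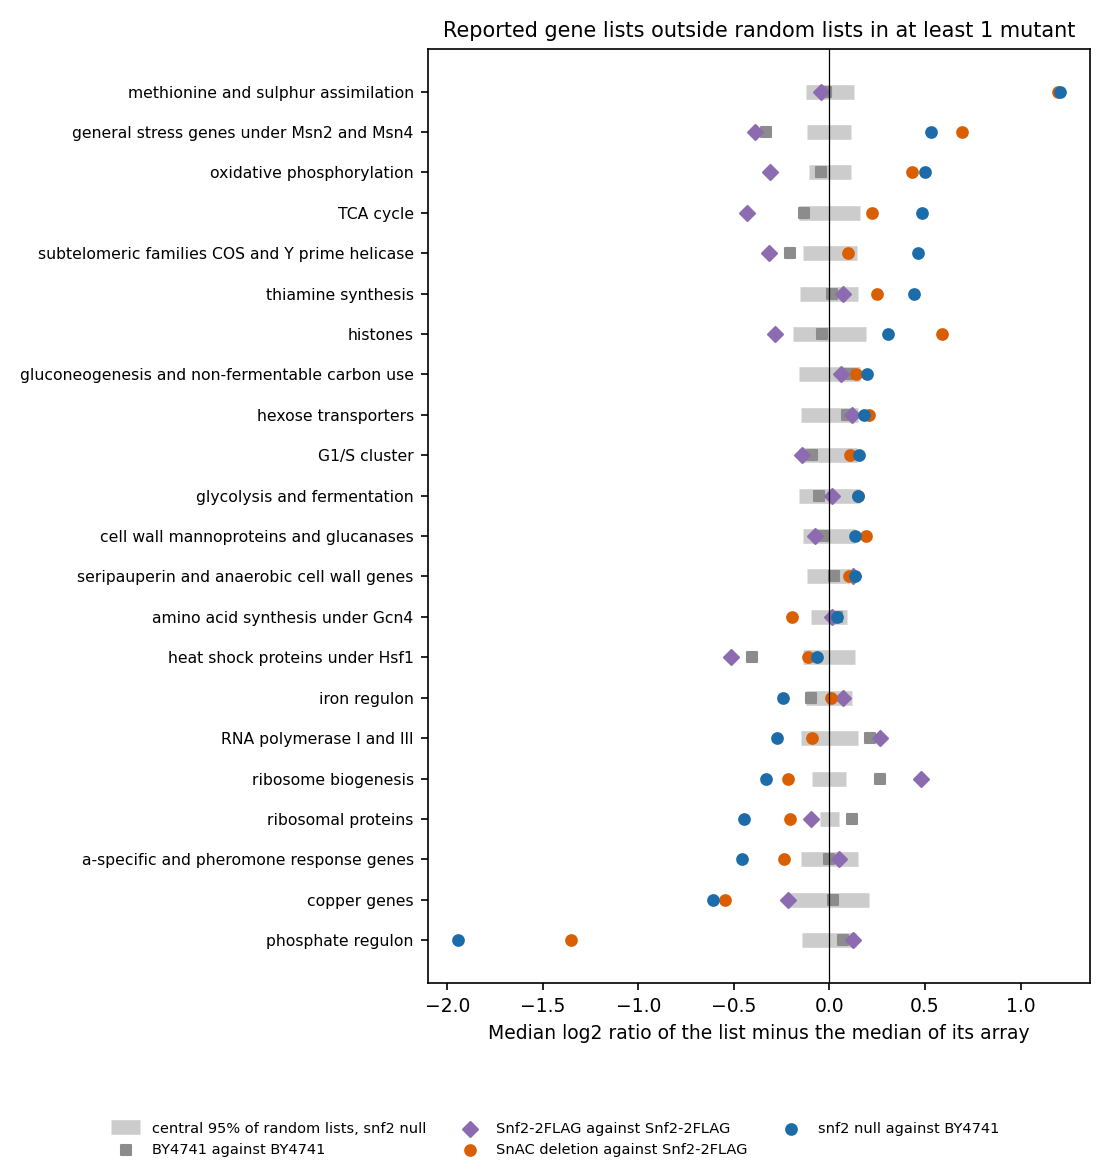
Median log2 ratio of each preset gene list minus the median of its array, for the lists outside the central 95% of random lists in at least 1 mutant, without 1 list that is not reported here. Phosphate genes lie lowest, at -1.94 in the null and -1.35 in the SnAC deletion, and methionine and sulphur genes highest, at 1.21 and 1.19, while the wild-type arrays lie close to 0 for both.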

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

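All tests in this part were chosen after the values they bear on, or closely related ones, had been seen. The genes listed here had opposite signs in the mutants on both scales and differed by at least 2-fold after centring, and the differences themselves were not tested, since each rests on 1 array per mutant.

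FIT2 differed between the null and the SnAC deletion by -2.27, FIT3 by -1.89 and PTR2 by -1.90, all lower in the null. The wild-type arrays, with the same strain in both channels, differed in the same direction by less. FIT2, FIT3 and PTR2 read -0.64, -0.375 and -0.34 on the BY4741 array, against 0.18, 0.185 and -0.001 on the Snf2-2FLAG array. FIT2 and FIT3 encode cell wall proteins of iron uptake, and PTR2 encodes the di- and tripeptide transporter. YOR338W, of which no function is given here, was higher in the null by 1.07, and the unnamed probe 3410 by 1.63.

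A candidate explanation for the FIT genes is a difference in iron supply between the cultures, which should shift the rest of the iron regulon too. The 20 other measured iron genes had a median difference of -0.10, and 95% of resamplings of these genes gave -0.28 to 0.02. This range describes the spread across genes on 1 array per mutant, not between cultures. It falls short of -0.50, the size set for this explanation. The median lay above -0.25, the bound set against the explanation, but the range reaches past that bound. A difference in supply therefore stays open. Among the siderophore transporters, SIT1, ARN1 and ENB1 differed by -0.83, -0.69 and -0.43, in the direction of the FIT genes, and ARN2 by 0.09. ARG1 and ARG4 were past the size rule in the null and not in the SnAC deletion. A candidate explanation is a Gcn4 programme that is higher throughout in the null than in the SnAC deletion. The 33 other genes of the Gcn4 list had a median difference of 0.22, resampled range 0.03 to 0.34. This range again fell short of 0.50. The median lay inside the bound set against this explanation, but the range reached past it. A weaker difference between the mutants stays open. ARG1 and ARG4 differed by 1.97 and 1.27, so a shift of that size does not account for their differences. Relative to the arrays, the whole list had a median of 0.04 in the null, inside random lists. In the SnAC deletion it was -0.19, below random lists. The list was thus low in the SnAC deletion and not raised in the null. Strain background and genotype remain open and untested for both.

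The SnAC deletion array as a whole lay at a median of -0.39. A constant offset from the scaling of the array could produce this, and so could an equal loss of mRNA per cell, since spike-ins were added by culture density. These cannot be told apart, because both would shift every feature alike and no spike-in value was analysed here. The count of features 2-fold higher depends on the choice, 20 as deposited and 51 after centring.

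The wild-type arrays shared low stress and heat shock genes and high ribosome biogenesis genes. A fixed bias of probes or dyes should appear on every array. Among 4686 features within 1.5-fold of the median in both mutants, the wild-type mean and the mutant mean correlated at -0.35. This cannot decide on such a bias, because the changes in the mutants ran opposite to the wild-type pattern. General stress genes had medians of 0.53 in the null and 0.70 in the SnAC deletion, and ribosome biogenesis genes -0.33 and -0.22. Such opposite changes could hide a probe bias, while a dye effect would cancel if both orientations entered each value equally. If the 2 channels of an array held RNA of separate cultures, which is not given in the sources used here, a difference in growth rate is another candidate explanation, and should move ribosomal protein genes with those for ribosome biogenesis. Their median was 0.12 in BY4741, above random lists, but -0.09 in Snf2-2FLAG, below them, which goes against growth rate as the whole cause on the latter array and leaves handling and other differences between the channels open.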

How the results depend on the processing

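Of these tests, removal of Ty reading frames, of unnamed probes and of features past the rule were chosen after the data were seen. At 1.5-fold, 260 features were higher and 169 lower in the null, 677 were lower in the SnAC deletion and 153 were lower in both. At 3-fold the null had 28 higher and 48 lower, the SnAC deletion 6 and 59, and 6 were higher and 41 lower in both. Looser and stricter folds change counts by construction. Centring the SnAC deletion array gave 51 higher and 70 lower, with 42 higher in both mutants, because its median lay at -0.39. Subtracting the wild-type array gave 155 higher in the null, and 33 higher and 489 lower in the SnAC deletion. It gave 31 higher in both and r of 0.79 between the mutants. Without centring, the wild-type medians of -0.12 and 0.10 move null values up and SnAC deletion values down. Other causes were not tested. Spearman's rho was 0.77, and r was 0.76 without features past the rule. Subtraction also turned 3 list medians. Heat shock proteins under Hsf1 turned to 0.38 and seripauperin genes to -0.057 in the SnAC deletion. Their medians on the Snf2-2FLAG array, -0.51 and 0.12, were larger in size than those in the SnAC deletion, -0.11 and 0.10. Subtracting that array therefore turns them. Hexose transporters in the null turned to -0.061, although their median was 0.09 on the BY4741 array and 0.18 in the null, and the cause was not tested. Counts stayed within 1.5 times of those reported without Ty reading frames, without unnamed probes, without features variable in wild type, and with features measured on all 4 arrays. Dropping the bound from the wild-type arrays moves nothing by construction, as the bound lies inside 2-fold. No paired analysis was possible because each group holds 1 sample, and leaving out samples in turn was not possible for the same reason. Signal over background is not given in the values used here, so its effect on dim probes is unknown.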

Other observations

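The lists in this part were drawn up after the data were seen. Pleiotropic drug resistance genes, which include those for drug efflux pumps and their regulators, had medians relative to the array of -0.60 in the null and -0.44 in the SnAC deletion. In each mutant 6 of 9 measured members lay below the array median and 3 above it, with PDR10 at 0.62 in the null. The efflux pump gene PDR5 was lower in both, at -2.10 in the null and -1.80 in the SnAC deletion relative to its array, and the polyamine exporter gene TPO1 read -1.28 and -1.08 in the same order. On the wild-type arrays PDR5 read -0.15 and 0.02. Trehalose and glycogen genes had medians of 0.31 in the null and 0.27 in the SnAC deletion, against -0.42 in BY4741 and -0.28 in Snf2-2FLAG. Apart from TSL1, their members stayed within the size rule in both mutants, with the trehalose synthase genes TPS1 and TPS2 at 0.70 and 0.56 in the null.

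Among genes of arginine metabolism, CAR2 was lower in both mutants at -3.12 in the null and -1.96 in the SnAC deletion, while CAR1, which encodes arginase, read 0.44 and 0.22, the SnAC values being relative to its array. The 8 measured genes of arginine synthesis had a median difference of 0.57 between the null and the SnAC deletion. Among unnamed probes, probe 3915 was the highest of them past the rule, at 2.61 in the null and 1.79 in the SnAC deletion as deposited, and probe 4814 the lowest, at -3.30 and -2.39.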
